A study of Mus musculus with 42 samples.

How the data were processed

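Lung RNA from C57BL/6J mice was sequenced as 42 libraries, 3 in each of 14 groups formed by 2 housing conditions and 7 collection times. Per the labels, mice spent 20 h per day for 2 days in SD cages or in home cages (Ctrl), from clock hour 14 to clock hour 10. Lungs were taken every 4 h for 24 h from clock hour 8, when lights came on (ZT0). Clock hour 10 lies between ZT0 and ZT4. These hours alone do not settle whether ZT0 came before or after the end of the last cage period. The series title gives sleep deficiency as the meaning of the treatment. Total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit. The labels name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build mm10. How these were set, the tool that made the values, the handling of strand and the handling of reads that map to several genes are not given in the sources used here.

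The deposited values are FPKM (fragments per kilobase of gene length, scaled by library), made by the authors, for 54532 genes, with a gene length per gene. Value times gene length was a whole multiple of 1 step per library, so read numbers could be recovered: 99.94% to 100% of values lay within 0.1 of a whole read. The steps were proportional to median-of-ratios size factors (largest deviation of the log factor 8.55e-05), so the deposited FPKM already carry that scaling in place of library totals. The recovered depth was 25285525 to 29790252 reads per library. A gene with few reads is limited by counting error, and no technical repeat of a library was marked. Of the 54532 genes, 16609 were at 0 in each library. Symbols of 27 genes that had turned into dates were restored from their gene IDs, and 103 symbols were borne by a second gene ID. Of the gene IDs, 54409 were found in GENCODE M21 and 98.33% of those had the same start and end. Coordinates are those of mm10.

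Gene tests used limma 3.58.1 (lmFit and eBayes with trend, moderated t and F statistics) under R 4.3.3, with the data.table package at version 1.17.8, on log2(FPKM + 1), for the 16962 genes with a mean FPKM of at least 0.5 over the 42 libraries. These genes held 99.62% of reads. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. A fold is 2 to the power of a difference of mean log2(FPKM + 1), so that for genes near 0 it is smaller than the ratio of FPKM. The model held 14 group means. Its contrasts were SD minus Ctrl averaged over the 7 times, SD minus Ctrl at each time, the 6 interaction contrasts between times (F test), and ZT24 minus ZT0 within each condition. The spread is shared by the 14 groups because each has 3 libraries.

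Rhythm was tested within each condition over 21 libraries by harmonic regression with a cosine and a sine of 24 h (F test), and a different rhythm by the interaction of condition with both terms. Amplitude is given in log2 units and peak time in h after ZT0, with standard errors by the delta method. Peak shifts were adjusted over the core clock genes. The number of genes called by 2 independent lists was set against the product of their shares.

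Gene lists (40, for pathways, lung cell types and tissues a lung dissection can carry along) were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, for the lists with at least 5 tested genes, adjusted over the lists within a contrast. A list was called on the preset correlation. Counts within a list are given over all genes tested and, where they differ, adjusted over the list alone. 2 more lists, for plasma cells and for mucous airway genes, were made after the values were seen, and their p is unadjusted. An exact sign-flip test of the 7 time-matched differences of list means was added.

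The comparisons, tests, lists, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule took, for the averaged effect, the 10 largest rises and 10 largest falls among called genes with a mean FPKM of at least 1 and the same side at 6 or more of 7 times. At each time it took the 2 largest rises and 2 largest falls whose 3 SD values did not overlap the 3 Ctrl values, which chance gives for 10% of genes. It also took the 10 largest amplitudes per condition, the 10 smallest p of different rhythm in each direction of amplitude, the 3 largest rises and falls from ZT0 to ZT24, the 5 smallest p of the interaction, each core clock and fatty acid oxidation gene, and the smallest-p members of the other lists. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were passed over.

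Settings chosen beforehand to set against the main ones were a pseudocount of 0.1, no filter on low values, rescaling by median of ratios, array weights, the replicate number as a block, each library left out in turn, only the 6 libraries of a time, no ZT24, a one-way F test in place of the cosine, and the estimated correlation. Added after seeing the data were scaling by total reads, limma-voom on recovered reads, the 14 group means as units, the averaged effect without ZT8, ZT12, ZT16 and ZT24, a plasma cell score as covariate, and the sign-flip test.

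The calls were tested on simulated data of the same size, with 50 genes changed at each size and a dispersion of 0.003. Apart from the set changes, the simulated libraries shared the same mean per gene, with no difference between groups. The unchanged genes called below therefore do not measure false calls where groups differ for other reasons. The averaged comparison recovered 90% of genes changed 1.2-fold and 100% of those changed 2-fold, with 8 unchanged genes called. The comparison at ZT8 recovered 24% at 1.2-fold and 98% at 2-fold, with 6 unchanged genes called. Rhythm in Ctrl was recovered for 72% of genes at an amplitude of 0.2 and 100% at 1, with 16 unchanged genes called, and the median absolute error of the peak at amplitude 1 was 0.0881 h. A different rhythm was recovered for 58% at 0.2 and 98% at 1, with 9 unchanged genes called. The interaction was recovered for 38% at 0.2 and 98% at 1, with 8 unchanged genes called. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Splice forms, alignments and sequence variants were not analysed here.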

Results

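Gene expression was measured in mouse lung by RNA sequencing, in mice kept in SD cages or home cages (Ctrl) and sampled at ZT0, ZT4, ZT8, ZT12, ZT16, ZT20 and ZT24. Each of the 14 groups held 3 libraries, with 25285525 to 29790252 recovered reads per library. The labels call the 3 libraries of a group biological replicates and do not say whether each is 1 animal or a pool. The libraries of a group lay close together: between groups lay 99.97% of the variance on the leading principal component, which held 38.97% of all variance. Within groups the median gene had an SD of 0.0845 log2 units in Ctrl and 0.0782 in SD, and between the group means of a condition 0.148 in both. The p-values below rest on the spread between the libraries of a group only. For the averaged effect and the rhythm counts, the count with the 14 group means as units is therefore given too. For the single times, the interaction and ZT24 against ZT0 no such count can be made, since 1 mean per group leaves no spread. Those counts rest on the spread between libraries alone.

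The comparison of SD with Ctrl averaged over the 7 times asks which lung genes are shifted in the mean over these times. Opposite differences at single times cancel in it. Genes of the glucocorticoid response list were among the largest rises. Pdk4, the kinase that shuts off pyruvate dehydrogenase, was 4.01-fold higher in SD (log2 2.00 ± 0.0252 SE, 7 of 7 times higher, adjusted p = 1.49e-34), and at ZT20 it reached 40.2 ± 1.2 FPKM (SD, n = 3) against 1.63 ± 0.26. Angptl4, a secreted inhibitor of lipoprotein lipase, was 4.69-fold higher (log2 2.23 ± 0.0255 SE, 7 of 7 times). Genes of plasma and B cells were among the largest falls: Jchain, the joining chain of IgM and IgA, changed by log2 -3.46 ± 0.0351 SE and was lower at 6 of 7 times. Its level at ZT16 was 452 ± 30 FPKM in Ctrl and 3.61 ± 0.27 in SD (SD, n = 3). Plasma cell genes were high in the Ctrl groups at ZT8, ZT12, ZT16 and ZT24, so the averaged fall reflects these Ctrl groups more than the others.

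In all, 11857 of 16962 genes were called in the averaged comparison, 5865 higher and 5992 lower in SD, of which 105 were at least 2-fold higher and 221 at least 2-fold lower. When the 14 group means were the units, 2875 genes were called (1553 higher, 1322 lower). Scaled by total reads, 4100 genes were called higher and 8026 lower, 33.8% higher against 49.5% as deposited. At each of the 7 times 493 genes were higher and 251 lower, where independent lists would share 0.912 and 0.812.

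The other named rises were Zbtb16, a zinc finger transcription factor (4.88-fold), Map3k6, a MAP kinase kinase kinase (4.77-fold), Fam107a (4.51-fold), Galnt15, a glycosyltransferase (4.20-fold), Rgcc, a regulator of cell cycle (3.88-fold), Tat, tyrosine aminotransferase (3.83-fold), Spp1, osteopontin (3.80-fold), and Retnlg, a neutrophil gene (3.76-fold). Each was higher at 7 of 7 times except Tat, at 6. Their SD over the 7 time-matched differences ran from 0.639 log2 units for Spp1 to 1.62 for Tat. Zbtb16 (chromosome 9, 48654297 to 48836222, ENSMUSG00000066687) was at 44.8 ± 1.9 FPKM in SD and 3.65 ± 0.58 in Ctrl at ZT20 (SD, n = 3). Map3k6 (chromosome 4, 133240818 to 133252929, ENSMUSG00000028862) was at 70.1 ± 2.5 and 8.28 ± 0.077 FPKM at ZT20. Angptl4 lies on chromosome 17 at 33773750 to 33781575 (ENSMUSG00000002289) and Pdk4 on chromosome 6 at 5483351 to 5496309 (ENSMUSG00000019577).

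The other named falls were Ccl8, a monocyte chemokine (log2 -2.79), Mzb1, a chaperone of plasma cells (-2.05), Agr2, a disulfide isomerase of mucous cells (-2.01), Cxcl13, the chemokine that attracts B cells (-1.82), Ly6d (-1.78), Spib, a transcription factor of B cells (-1.72), Ubd (-1.65), Plac8 (-1.59) and Scn3b, a sodium channel subunit (-1.56). Jchain lies on chromosome 5 at 88519809 to 88527891 (ENSMUSG00000067149). Cxcl13 (adjusted p = 0.0773) and Ubd (adjusted p = 0.0638) were not called with group means as units, and the other 8 falls were. These 2 genes also lost their call without ZT8, ZT12, ZT16 and ZT24, where Cxcl13 stood at log2 0.08 and Ubd at -0.01.

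Of 40 fixed lists, 37 held enough genes for a test, and 27 were called for the averaged effect, 13 higher and 14 lower in SD. With an estimated correlation 19 of the 27 held. By the exact sign-flip test over 7 times none was called, its smallest possible p being 0.0156 and its smallest adjusted p 0.0526. Lists that moved the same way at each time stand at that floor, so the lack of calls follows in part from the few times. Among them the list mean was higher in SD at 7 of 7 times for glucocorticoid response and at 0 for proliferation and B cell genes. The called lists differed in how many genes were called with group means as units. These were 13 of 13 B cell, 12 of 14 T cell and 10 of 10 MHC class II genes. They were only 4 of 12 neutrophil, 2 of 18 NRF2, 1 of 6 mesothelial, 1 of 11 cardiac muscle, 0 of 14 ciliated and 0 of 10 erythroid genes.

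**Figure D1:**
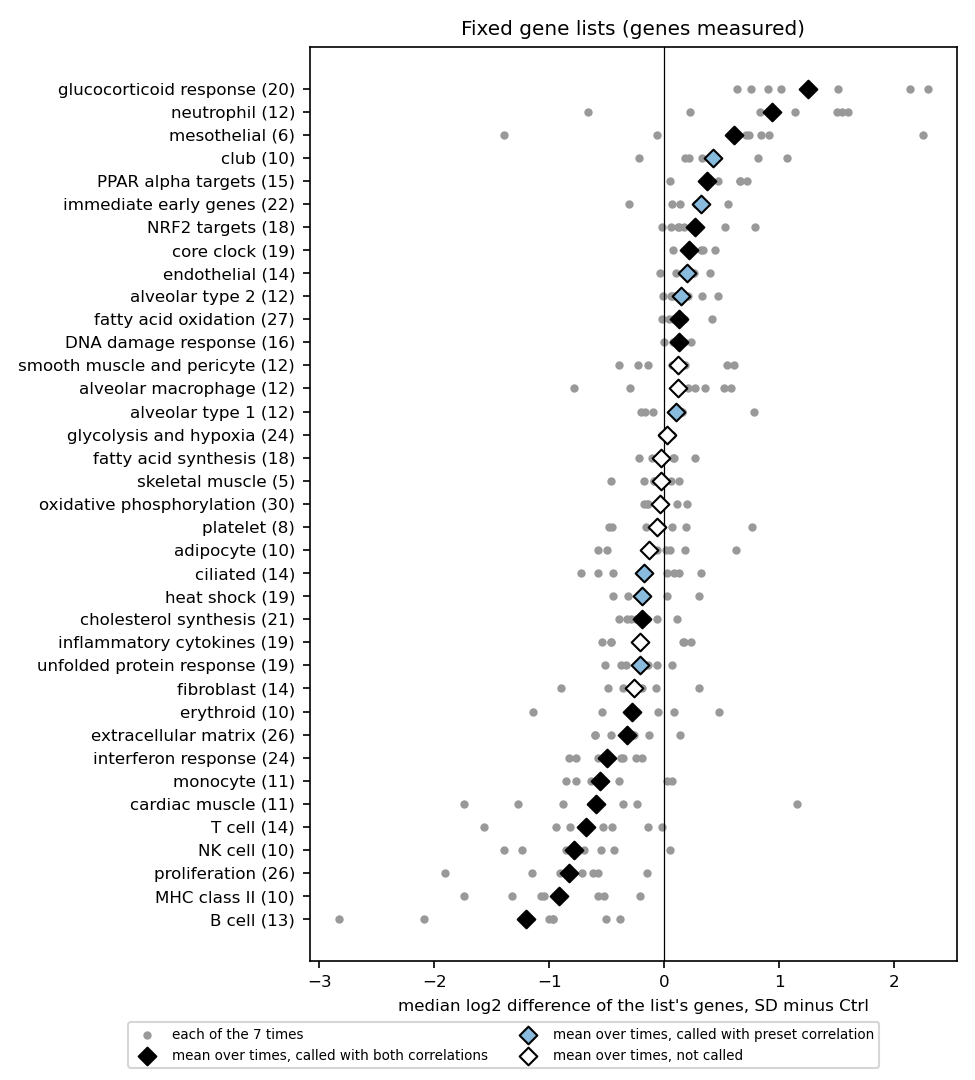
Median log2 difference, SD minus Ctrl, of the genes of each list on the horizontal axis, with lists as lines down the vertical axis. Diamonds are averages over times (black called with both correlations, blue with the preset one only, white not called) and grey dots the 7 times; glucocorticoid response stands at 1.25 and B cell at -1.21.

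Glucocorticoid response genes were higher as a group: 19 of 20 rose and 1, Lcn2, fell (median log2 1.25, adjusted p = 6.86e-16, and 2.88e-07 with an estimated correlation). Fkbp5, a co-chaperone of steroid receptors, was 3.48-fold higher and Cdkn1a, an inhibitor of cyclin-dependent kinases, 3.57-fold higher. Of the 20, 15 were called on group means. The list median was highest at ZT20 (2.29, 20 of 20 higher) and ZT8 (2.14, 19 of 20 higher). It holds Pdk4 and Angptl4, which the PPAR alpha list also holds.

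Fatty acid oxidation, the process in the title of the series, was represented by 27 of 29 listed genes. Of these 21 rose, 3 fell (Acsl3, log2 -0.06, Acsl5, -0.23, and Acads, -0.12) and 3 were not called (Hadha, 0.02, Eci1, -0.04, and Decr1, -0.04), with equal counts adjusted over the list alone. The list median was log2 0.13 (adjusted p = 0.000188, and 0.0167 with an estimated correlation). Acaa1b, a peroxisomal thiolase, rose 2.11-fold and by like amounts at each time (log2 1.07, SD over 7 differences 0.121). It stood between 5.11 and 8.70 FPKM in the Ctrl groups and between 12.1 and 21.2 in the SD groups. Acaa1b lies on chromosome 9 at 119148023 to 119157093 (ENSMUSG00000010651). Cpt1a, the carnitine acyltransferase that admits long-chain fatty acids to mitochondria (chromosome 19, 3323301 to 3385732, ENSMUSG00000024900), rose 1.42-fold, with 52.9 ± 1.9 FPKM in SD and 23.1 ± 1.1 in Ctrl at ZT20 (SD, n = 3).

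Among the other risers were Eci2 (1.41-fold), Acaa2 (1.32-fold), Acadl (1.25-fold) and Slc25a20, the carnitine carrier (1.22-fold). On group means 5 of the 27 genes were called, Acaa1b among them (adjusted p = 0.000241) and Cpt1a not (0.0683). By fry, which asks whether genes of a list move on balance 1 way without comparing them with other genes, the adjusted p was 2.24e-23, and for change in either direction 9.32e-37. Both fry values were under 0.05 for each list tested, so fry does not set this list apart. For fatty acid synthesis and skeletal muscle, which camera did not call, the fry adjusted p was 7.10e-17 and 0.0313. By time, the list was called higher at ZT0 (16 higher, 1 lower), ZT8 (17 and 4), ZT12 (12 and 3), ZT16 (15 and 1) and ZT20 (19 and 1, median 0.41). With an estimated correlation the adjusted p was 0.00606 at ZT0, 0.0646 at ZT8, 0.160 at ZT12, 0.0524 at ZT16 and 0.00592 at ZT20. It was not called at ZT4 (4 higher and 9 lower, adjusted p = 0.727) or ZT24 (11 and 4, 0.182). Scaled by total reads, Acsl4, Hadh and Etfa stood at log2 -0.00128, -0.01 and -0.00578 without a call, and Hadha at -0.05 with a call. Cpt2, Ehhadh and Etfb also lost their calls under that scaling, and Eci1 and Decr1 were called lower, each at -0.11. Without ZT8, ZT12, ZT16 and ZT24 Acsl4, Acadm, Acads, Acaa1a, Etfb and Hadh lost their calls, Hadha was called higher (0.05, adjusted p = 0.0378) and Decr1 lower (-0.13).

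**Figure D2:**
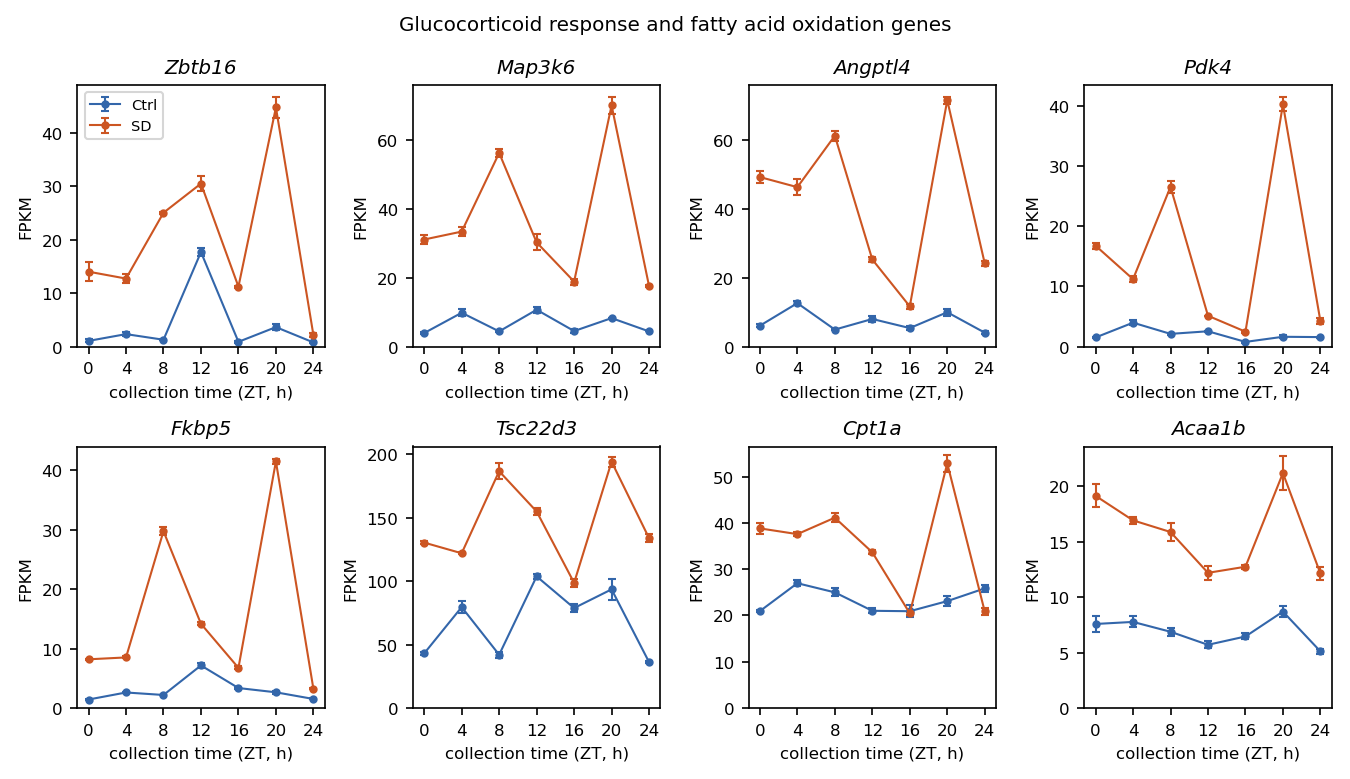
FPKM (vertical axes) against collection time in h (horizontal axes) for 8 glucocorticoid response and fatty acid genes, with points for group means of 3 libraries and bars for the SD, Ctrl and SD drawn apart. Pdk4 in SD is at 40.2 FPKM at ZT20 and at 2.48 at ZT16.

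PPAR alpha targets, genes of lipid handling, were higher too: 12 of 15 rose and 2 fell (median 0.37, adjusted p = 1.50e-05, and 0.000699 with an estimated correlation). Acot1, an acyl-CoA thioesterase, rose 2.3-fold and Ucp2, a mitochondrial carrier, 1.92-fold. Of 18 NRF2 targets 16 rose and 1 fell (median 0.26, adjusted p = 1.17e-05, and 0.0105 with an estimated correlation), among them the glutathione transferases Gsta3 (1.77-fold) and Gstm1 (1.56-fold). Of 16 DNA damage response genes 10 rose and 2 fell (median 0.13, adjusted p = 0.00473, and 0.0105 with an estimated correlation). Without ZT8, ZT12, ZT16 and ZT24 that list had an adjusted p of 0.115. Cholesterol synthesis genes fell, 18 of 21, with 1 riser, Pmvk (2.04-fold), and 2 risers adjusted over the list alone (median -0.19, adjusted p = 0.000188, and 0.00103 with an estimated correlation). Stard4, a sterol carrier, changed by log2 -0.64 and Cyp51 by -0.54. Of 22 immediate early genes 14 rose and 5 fell (median 0.32, adjusted p = 0.00238), with Fos at 0.48 and Egr3 at -0.86. That call was lost with an estimated correlation (adjusted p = 0.107), and the median was -0.06 without ZT8, ZT12, ZT16 and ZT24.

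Genes of proliferation fell without exception, 26 of 26 (median -0.83, adjusted p = 3.36e-16, and 0.000143 with an estimated correlation). Mki67, a marker of cycling cells, changed by log2 -1.19, with 1.68 ± 0.069 FPKM in SD and 16.2 ± 0.76 in Ctrl at ZT16 (SD, n = 3). Top2a changed by -1.24 and Cdk1 by -0.996, and 23 of the 26 were called with group means as units. Each of 24 interferon response genes fell (median -0.50, adjusted p = 1.99e-12, and 1.44e-05 with an estimated correlation), with Gbp3 at -0.95 and Cxcl9 at -1.26. On group means 19 of the 24 were called. Each of 10 MHC class II genes fell (median -0.92, adjusted p = 1.04e-09, and 0.00103 with an estimated correlation), with H2-Aa at -0.91 and Ciita, the transactivator of the class, at -1.16.

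Lymphocyte genes were lower in SD. Of 13 B cell genes all fell (median -1.21, adjusted p = 1.99e-12, and 1.44e-05 with an estimated correlation), and all 13 were called with group means as units. Ighm, the IgM heavy chain, changed by log2 -1.72. Of 14 T cell genes 13 fell (median -0.68, adjusted p = 2.12e-07, and 0.000392 with an estimated correlation), with Lck at -0.99. Of 10 NK cell genes all fell (median -0.78, adjusted p = 2.33e-06, and 0.000552 with an estimated correlation), with the granzyme Gzma at -1.19. Of 11 monocyte genes 9 fell and 2 rose (median -0.56, adjusted p = 0.000371, and 0.00151 with an estimated correlation), with Ccr2 at -0.89 and Ace 1.51-fold higher. Neutrophil genes went the other way: 10 of 12 rose and 1 fell (median 0.93, adjusted p = 1.76e-06, and 0.00203 with an estimated correlation), with Il1r2 2.89-fold and Csf3r, the G-CSF receptor, 1.80-fold higher. With group means as units 4 of the 12 neutrophil genes were called. At ZT24 the neutrophil list was lower (2 higher and 9 lower, median -0.66, adjusted p = 2.71e-05, and 0.00499 with an estimated correlation).

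Plasma cell genes set 4 Ctrl groups apart, and mucous airway genes were high in the same groups. Those at ZT8, ZT12, ZT16 and ZT24 carried high plasma cell genes, with medians of log2 3.42, 4.87, 5.34 and 1.83 above Ctrl ZT0, and high mucous genes, with 4.14, 3.84, 2.52 and 2.83. In both lists, made after the values were seen, each gene fell in SD on average over the times, 10 of 10 for plasma cells (median -2.57) and 11 of 11 for mucous airway (median -2.34), by the limma test of each gene. Their direction is not independent evidence, since the lists were chosen on these libraries. These averages are not shared by all times. Mucous genes were also higher at Ctrl ZT4 (mean log2 2.94) and SD ZT8 (3.03) than at Ctrl ZT0 (1.32), and at ZT4 11 of 11 were lower in SD (median -1.50). At ZT0 8 mucous genes were higher in SD and 0 lower (median 0.63), and at ZT20 3 mucous genes were higher and 0 lower, and 4 plasma cell genes higher and 3 lower. Ighg2b, an IgG heavy chain, was at 897 ± 19 FPKM in Ctrl and 0.604 ± 0.17 in SD at ZT16 (SD, n = 3). Reads of immunoglobulin genes can be shared between related genes, so the split between them is uncertain. Without those 4 times the B cell list stood at -0.65, the T cell list at -0.19, MHC class II at -0.62 and proliferation at -0.43, each still called, and 9379 genes were called in all.

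**Figure D3:**
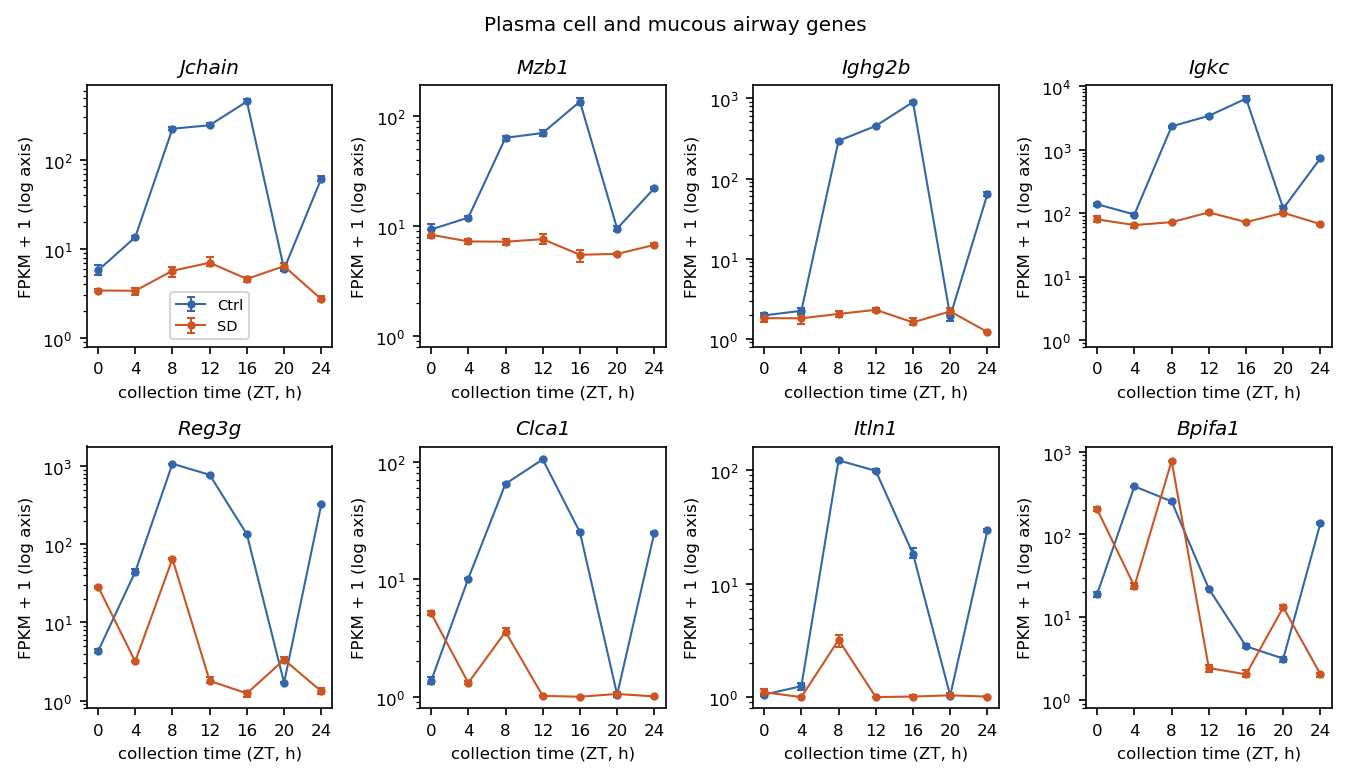
FPKM + 1 on a log axis (vertical) against collection time in h (horizontal) for 4 plasma cell and 4 mucous or airway secretory genes, points for group means and bars from the lowest to the highest of 3 libraries. Reg3g is at 777 FPKM in Ctrl and 0.787 in SD at ZT12, while Bpifa1 is highest in SD at ZT8, at 770.

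Extracellular matrix genes fell, 19 of 26 with 4 risers (median -0.32, adjusted p = 9.47e-06, and 0.00708 with an estimated correlation), with the collagens Col3a1 at log2 -1.16 and Col1a2 at -0.67. Lox, a cross-linking oxidase, rose 2.89-fold. Of 14 fibroblast genes 8 fell and 5 rose (median -0.26, adjusted p = 0.0576). All 6 mesothelial genes rose (median 0.61, adjusted p = 3.49e-05, and 0.000552 with an estimated correlation), with Upk3b at 1.08 and Upk1b at 0.71. The mesothelial list mean was higher in SD at 6 of 7 times. Without ZT8, ZT12, ZT16 and ZT24 the mesothelial median was -0.13 with no call. Of 10 club cell genes 8 rose and 2 fell (median 0.42, adjusted p = 0.00603), with Cyp2f2 1.59-fold higher and Scgb3a1 at log2 -2.03. The club list mean was higher in SD at 4 of 7 times. Of 12 alveolar type 2 genes 9 rose and 2 fell, 3 adjusted over the list alone (median 0.14, adjusted p = 0.0135), with Sftpb 1.38-fold higher. Of 12 alveolar type 1 genes 7 rose and 2 fell (median 0.10, adjusted p = 0.0493). Of 14 endothelial genes 10 rose and 4 fell (median 0.20, adjusted p = 0.0266), with Ramp2 1.71-fold and Vwf 1.49-fold higher. Of 14 ciliated cell genes 12 fell and 1 rose (median -0.18, adjusted p = 0.00603), with Foxj1 at -0.30. These 5 calls were lost with an estimated correlation, where the adjusted p was 0.0758 for club, 0.0751 for type 2, 0.0741 for type 1, 0.0758 for endothelial and 0.0585 for ciliated genes. Scaled by total reads the type 1 list had an adjusted p of 0.188. Without ZT8, ZT12, ZT16 and ZT24 its median was -0.11 with a call (adjusted p = 0.0474), and the type 2, endothelial and ciliated lists lost their calls.

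Of 11 cardiac muscle genes, a tissue a lung dissection can carry along, all fell (median -0.59, adjusted p = 3.09e-06, and 0.00322 with an estimated correlation), with Nppa at log2 -1.19 and Myl4 at -0.89. By time the cardiac median went from 1.15 at ZT0 to -1.74 at ZT24, and without ZT8, ZT12, ZT16 and ZT24 it was 0.02. Of 10 erythroid genes 8 fell and 1 rose (median -0.28, adjusted p = 0.00807, and 0.0479 with an estimated correlation), with Alas2 at -0.37. Heat shock genes fell in 13 of 19 cases and rose in 6 (median -0.19, adjusted p = 0.0188, and 0.107 with an estimated correlation), with the collagen chaperone Serpinh1 at -0.70 and Hsp90aa1 at -0.32. Reads can be shared between Hspa1a and Hspa1b and between the Hba genes. Of 19 genes of the unfolded protein response 12 fell and 6 rose (median -0.21, adjusted p = 0.0188, and 0.107 with an estimated correlation), with Pdia4 at -0.65 and Hspa5 at -0.46.

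The lists without a call were smooth muscle and pericyte (6 higher, 4 lower, adjusted p = 0.280), alveolar macrophage (8 and 4, 0.367), glycolysis and hypoxia (9 and 6, 0.393), fatty acid synthesis (7 and 9, or 8 and 9 adjusted over the list alone, 0.480), and skeletal muscle (1 and 2, 0.774). Oxidative phosphorylation (4 higher, 13 lower, adjusted p = 0.267), platelet (3 and 4, 0.515) and inflammatory cytokines (5 and 10, 0.0775) were not called either. With no filter on low values inflammatory cytokines (median -0.22, adjusted p = 0.00245) and fibroblast genes (-0.26, 0.0101) were called lower. Without ZT8, ZT12, ZT16 and ZT24 alveolar macrophage (0.46, 3.97e-05) and adipocyte genes (0.16, 0.0231) were called higher, and platelet (-0.15, 0.0345) and fibroblast genes (-0.23, 0.0259) lower. Scaled by total reads, oxidative phosphorylation was called lower (median -0.11, adjusted p = 0.0352). The adipocyte list (4 higher, 5 lower, adjusted p = 0.958) had a median of -0.13 and a mean of 0.05. Cold inducible RNA binding (2 genes), cartilage (2) and thymus (3) had too few genes for a test.

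The comparison at each time asks how the difference between SD and Ctrl depends on the collection time. Clock hour and time relative to the cage period change together over these times. Their effects cannot be told apart. At ZT0, Alb, the plasma protein albumin, stood at 57.7 ± 2.3 FPKM in SD and 1.13 ± 0.045 in Ctrl (27.6-fold on log2(FPKM + 1), adjusted p = 6.88e-27; SD, n = 3). Apoa1, an apolipoprotein, was 16.4-fold higher. Both are abundant in liver, and whether liver RNA was carried along in this group was not tested. At the same time Plac8 changed by log2 -2.13 and the mitochondrial tRNA gene mt-Tr by -1.70 (adjusted p = 0.0399). In all 6393 genes were called, 3054 higher and 3339 lower (2557 and 4020 scaled by total reads). At ZT4, Cyp26b1, which breaks down retinoic acid, was 4.58-fold and Spp1 4.34-fold higher. Bpifa1, a secreted airway protein, changed by -4.01 and Reg3g, an antibacterial lectin, by -3.81. At ZT4 6656 genes were called, 3253 higher and 3403 lower (3728 and 2901 scaled by total reads). The mt-Tr call was lost with array weights and with no filter.

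At ZT8 and ZT12 the falls were larger than the rises. At ZT8 Tat was 11.8-fold and Fam107a 11.5-fold higher, while Jchain changed by log2 -5.31 and Itln1, a lectin of mucous cells, by -5.26. In all 9506 genes were called, 4605 higher and 4901 lower (3294 and 6414 scaled by total reads), of which 316 were at least 2-fold higher and 533 at least 2-fold lower. At ZT12 Csf3r was 5.47-fold and Stfa2l1, a stefin of neutrophils, 5.30-fold higher. Reg3g changed by -8.77, from 777 ± 21 FPKM in Ctrl to 0.787 ± 0.19 in SD (SD, n = 3), and Gp2 by -6.87. At ZT12 8286 genes were called, 4146 higher and 4140 lower (3379 and 4812 scaled by total reads).

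At ZT16 Upk3b, a mesothelial gene, was 13.1-fold higher and Mir143, a microRNA gene of smooth muscle, 8.75-fold (adjusted p = 3.08e-07), while Reg3g changed by log2 -6.78 and Jchain by -6.62. In all 9524 genes were called, 4934 higher and 4590 lower (4146 and 5389 scaled by total reads), and 816 were at least 2-fold lower. At ZT20, where the plasma cell and mucous medians stood at 0.07 each, 10423 genes were called, 5604 higher and 4819 lower. Tat was 21.5-fold and Pdk4 15.7-fold higher, and Apln, an angiogenic peptide, changed by -3.17 and Scn3b by -2.93. Scaled by total reads the median of all genes at ZT20 moved to -0.14 and the counts to 3215 higher and 7619 lower. At ZT24 Per1, a clock repressor, was 6.18-fold higher, at 40.5 ± 0.58 FPKM against 5.71 ± 0.11 (SD, n = 3), and Angptl4 5.0-fold higher. Reg3g changed by -7.96 and Bpifa1 by -6.08. At ZT24 7933 genes were called, 4143 higher and 3790 lower (2663 and 5257 scaled by total reads).

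**Figure D4:**
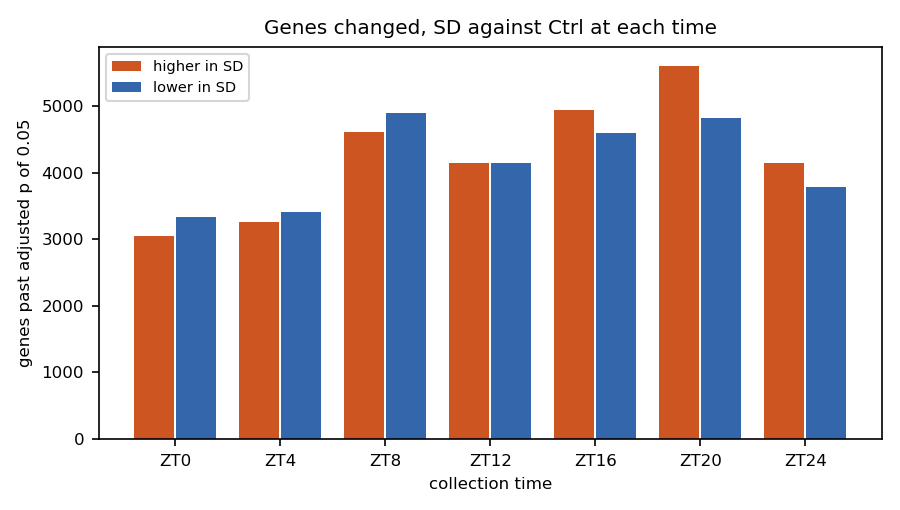
Number of genes called (vertical axis) against collection time (horizontal axis), with bars for genes higher and genes lower in SD than in Ctrl. The count runs from 6393 at ZT0 to 10423 at ZT20.

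The size of the difference depended on the collection time for 13850 of 16962 genes (interaction F test), and 6209 genes were higher at some time and lower at another. The smallest p belonged to mucous and airway secretory genes. Clca1, a secreted protein of mucous cells, ranged from log2 -6.69 at ZT12 to 1.92 at ZT0 (adjusted p = 1.60e-40), and Reg3g from -8.77 at ZT12 to 2.76 at ZT0. Scgb3a1, a secretoglobin, ranged from -5.05 at ZT12 to 1.73 at ZT20, Bpifa1 from -6.08 at ZT24 to 3.39 at ZT0, and Muc5b, a gel-forming mucin, from -4.45 at ZT12 to 1.15 at ZT0. Of 117 named genes 114 passed this test.

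Rhythm was tested because the series describes circadian profiles. A cosine over these times also takes up changes with time relative to the cage period. In SD such changes cannot be told apart from a rhythm or a shift of its peak. In Ctrl lungs 9767 genes fitted a 24 h cosine. The largest amplitudes belonged to Bpifa1 (log2 3.70), Reg3g (3.58), Itln1 (2.82), Gp2 (2.76), Clca1 (2.69), Jchain (2.66), Cd177, a neutrophil surface gene (2.57), Nr1d1, the clock repressor REV-ERB alpha (2.54), Dbp, a clock output factor (2.45), and Tff2, a trefoil factor (2.33). Of these 10, only Nr1d1 and Dbp are in the core clock list. The other 8 were high in the Ctrl groups at ZT8, ZT12 or ZT24, the Bpifa1 level being 250 ± 8.4 FPKM at ZT8, and Reg3g was 76.5-fold higher at ZT24 than at ZT0, the same clock hour. A fit to the group means called 385 genes in Ctrl. Peaks fell in each 4 h bin, from 1105 genes at 8 to 12 h to 2038 at 12 to 16 h.

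In SD lungs 1560 genes fitted a 24 h cosine, and 1239 of them did so in both conditions, where independent lists would share 898. The SD count was 3909 with array weights and 4288 with the plasma cell score as covariate. The largest amplitudes belonged to Dbp (log2 2.09), Cfd, adipsin (1.75), Myh6, a cardiac myosin (1.62), Nr1d1 (1.58), Myl7, an atrial myosin light chain (1.50), Sln, sarcolipin (1.49), Mb, myoglobin (1.40), Car3, a carbonic anhydrase of fat and muscle (1.39), Spon2, a matrix protein (1.33), and Tcap (1.25). Cardiac genes varied more between groups than within them in both conditions, with an SD of 0.964 between and 0.106 within in SD, and 0.664 and 0.118 in Ctrl. A fit to the group means called 2 genes in SD, and 509 had an unadjusted p under 0.05. Of 100 orders of the 7 SD groups over the times, 76, the real one included, gave as many genes. With a one-way F test in place of the cosine 13516 SD genes changed over time.

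The rhythm differed between conditions for 5140 genes, with a lower amplitude estimate in SD for 4428 and a higher one for 712. The test takes amplitude and peak hour together. The amplitude difference alone was not tested, so its direction is that of the estimates. Csf3r went from log2 0.71 in Ctrl to 0.37 in SD (adjusted p = 2.43e-11), Appl2, an endosomal adaptor, from 0.48 to 0.10, Anxa8, an annexin, from 0.996 to 0.13, and Pdgfrb, the pericyte receptor, from 0.48 to 0.11. The ciliary genes Ccdc113 (0.74 to 0.22), Cfap126 (0.76 to 0.28) and Rsph1 (0.75 to 0.30) also had lower amplitudes, as did Fam81b (0.83 to 0.21), Ppp1r36 (0.73 to 0.22) and Cyp7b1, an oxysterol hydroxylase (0.49 to 0.11). Higher amplitude estimates were found for Wfdc1 (0.08 to 0.49), Angptl7 (0.30 to 0.68), Ivd, an enzyme of leucine breakdown (0.07 to 0.25), Myl9 (0.17 to 0.37), Fabp1 (0.29 to 0.47), Ier3 (0.41 to 0.48) and Ssx2ip (0.19 to 0.22). The Ssx2ip difference, 0.0267, was smaller than that of Gata5, 0.0351. Gata5, Cobl and Gata6 differed mainly in the hour of the peak, for Cobl 2.21 h in Ctrl and 18.5 h in SD. Their amplitude differences of 0.04, 0.00167 and 0.02 changed sign without ZT24, and those of Cobl and Gata6 also when scaled by total reads. Among genes rhythmic in Ctrl the median amplitude was 0.199 in Ctrl and 0.0895 in SD. These genes were chosen on the Ctrl fit, which favours a higher amplitude in Ctrl, so this gap is not independent evidence. On group means limma called 0 genes for a different rhythm, with 1680 at an unadjusted p under 0.05.

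Most core clock genes were rhythmic in both conditions. Of 19, 17 were rhythmic in Ctrl and 15 in SD, all 15 of them in both, and 18 and 15 adjusted over the list alone. On group means, adjusted over the list alone, 14 were rhythmic in each condition. Arntl, the activator BMAL1, peaked at 22.3 h in Ctrl and 22.2 h in SD, with amplitudes of log2 1.06 and 0.99. Nr1d1 (chromosome 11, 98767932 to 98775333, ENSMUSG00000020889) reached 63.8 ± 3.7 FPKM in Ctrl and 63.0 ± 3.0 in SD at ZT8, but at ZT20 stood at 1.52 ± 0.047 in Ctrl and 9.64 ± 0.39 in SD (SD, n = 3). Its amplitude was 2.54 in Ctrl and 1.58 in SD, and its peak to trough fold 33.8 and 8.93. Dbp (chromosome 7, 45705088 to 45710203, ENSMUSG00000059824) was at 77.1 ± 2.3 FPKM in Ctrl and 38.8 ± 2.6 in SD at ZT8, with peak to trough folds of 30.0 and 18.1. Not rhythmic, adjusted over all genes, were Rora (adjusted p = 0.723 in Ctrl and 0.365 in SD) and Ciart (0.0579 and 0.457) in both conditions and, in SD, Cry2 (0.421) and Per1 (0.979). Over the list alone Ciart was rhythmic in Ctrl (0.0362).

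**Figure D5:**
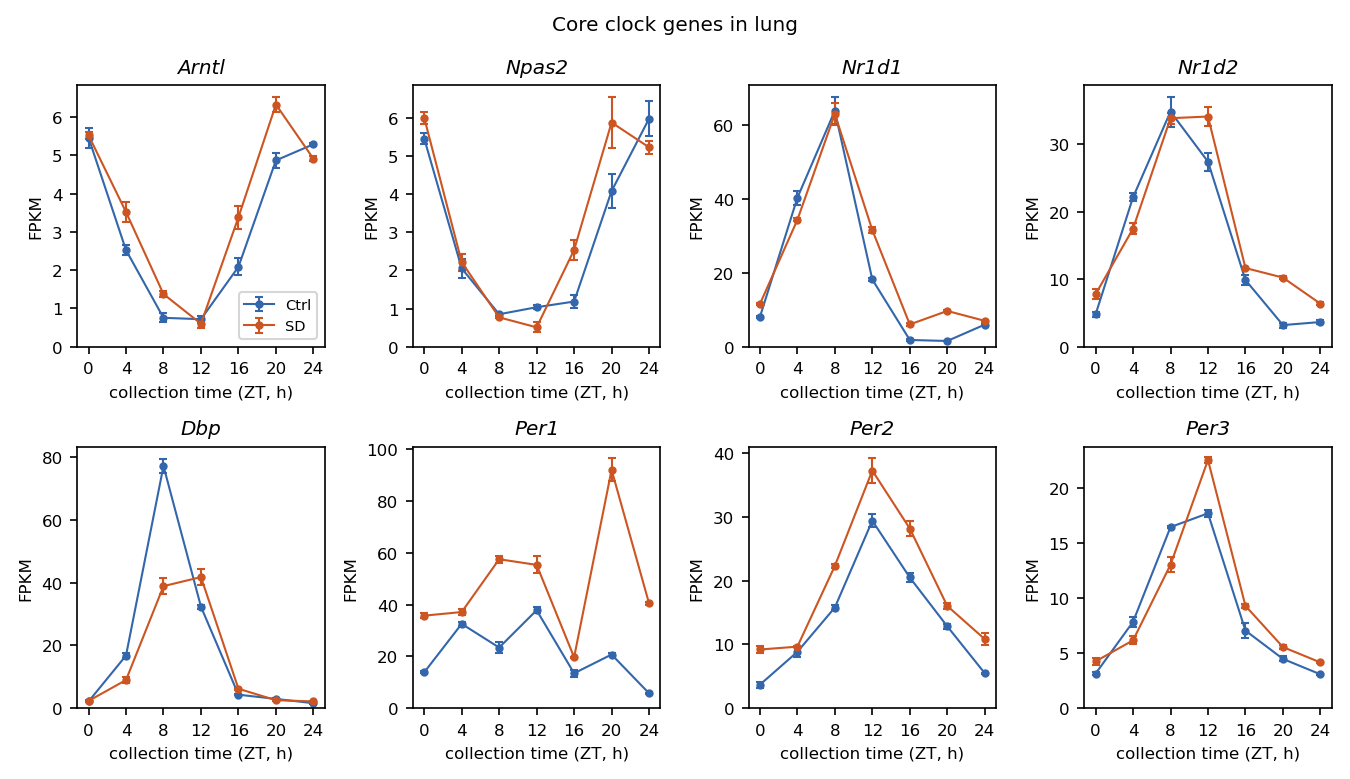
FPKM (vertical axes) against collection time in h (horizontal axes) for 8 core clock genes, points for group means of 3 libraries and bars for the SD, Ctrl and SD drawn apart. Nr1d1 peaks at 63.8 FPKM in Ctrl and 63.0 in SD at ZT8, and at ZT20 is at 1.52 and 9.64.

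A different rhythm was called for 8 of the 19 clock genes, 5 with a lower and 3 with a higher amplitude estimate in SD, and for 8 adjusted over the list alone. Among the 8, Nr1d2 had an amplitude of log2 1.71 in Ctrl and 1.13 in SD. Per1 (chromosome 11, 69095217 to 69109960, ENSMUSG00000020893) had amplitudes of 0.74 and 0.06 and was not called for a different rhythm (adjusted p = 0.107, and 0.0807 over the list alone). Over the list the median ratio of amplitudes was 0.891. Among the 15 genes rhythmic in both, the median peak shift was 0.755 h later in SD (mean 0.722, SD 1.1), but 0.362 h with array weights and 0.399 h with the plasma cell score as covariate. A later peak was called for 7: Bhlhe40 (2.82 ± 0.645 h, SE), Tef (2.49 ± 0.681), Hlf (2.20 ± 0.546), Per3 (1.17 ± 0.285), Nr1d1 (0.865 ± 0.287), Dbp (0.817 ± 0.285) and Nr1d2 (0.755 ± 0.314, adjusted p = 0.0496). Npas2 peaked earlier (-0.963 ± 0.313 h). On group means none of these 8 shifts was called by limma (adjusted p from 0.338 to 0.529). The Nr1d1 shift was 0.539 h without ZT24 (adjusted p = 0.127), array weights ended the calls of Npas2, Dbp and Tef, and a plasma cell score as covariate those of Nr1d1 and Dbp (0.264 h for Dbp). The Nr1d2 shift lost its call under each other setting with all libraries kept, except rescaling by median of ratios (adjusted p from 0.0528 to 0.529).

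The mean level of the clock list was higher in SD: 16 rose, 2 fell (Dbp, log2 -0.11, and Bhlhe40, -0.27) and Bhlhe41 was not called (-0.01, adjusted p = 0.743). Per1 was 2.33-fold, Cry2 1.60-fold, Nr1d1 1.58-fold, Tef 1.56-fold and Per2 1.44-fold higher (list adjusted p = 3.45e-05, and 0.000392 with an estimated correlation). The Npas2 rise lost its call with a pseudocount of 0.1 (adjusted p = 0.0883), with total reads (0.188) and with voom (0.209). The Ciart rise lost its call with total reads (0.448), and Ciart was called lower, at -0.26, without ZT8, ZT12, ZT16 and ZT24. On group means 5 of the 19 were called.

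ZT24 and ZT0 are the same clock hour 1 day apart, so their comparison asks how far the groups of a condition differ at that hour. SD at ZT0 had already been in the SD cages and is not an untreated baseline, so likeness to it would not mean recovery. In Ctrl 2190 genes differed, 1177 higher and 1013 lower at ZT24. Reg3g was 76.5-fold, Itln1 28.0-fold and Gp2 24.7-fold higher, and the immediate early genes Fosb (log2 -2.20) and Nr4a1 (-1.73) and the microRNA gene Mir23a (-2.09, adjusted p = 0.00232) were lower. In SD 6537 genes differed, 3456 higher and 3081 lower. Hspa1b, a heat shock protein, was 3.61-fold, Slpi, a protease inhibitor, 3.52-fold and Mir6999 3.12-fold higher (adjusted p = 0.0249 for Mir6999, lost with array weights and with no filter). Bpifa1 (-6.62), Alb (-5.09) and Reg3g (-4.46) were lower. Alb was the largest named rise in SD at ZT0, where liver RNA carried along was not tested. Of the genes tested, 5491 changed from ZT0 to ZT24 by amounts that differed between the conditions.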

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

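The tests of a repeated library, of a shared tissue sample or pool in each condition apart, a 24 h rhythm of plasma cell genes, lymphoid tissue, conducting airway and a stopped clock were chosen only after the result was seen. Groups of 3 libraries were not examined for outlying libraries. The difference between SD and Ctrl depended on the time for 13850 genes by the test of the interaction. Of 100 splits that exchanged libraries between conditions within times, 1, the real one, gave as many (highest other 6312). These exchanges part libraries of a group that lie close together, which widens the spread within groups and favours lower counts. They speak for differences between groups and, if the 3 libraries of a group come from 1 pool, not for animals. The range of the difference over the 7 times was 8.61 log2 units for Clca1, 11.5 for Reg3g, 6.78 for Scgb3a1, 9.47 for Bpifa1 and 5.605 for Muc5b. Rhythm differed between the conditions for 5140 genes by the test of the difference, and 1 of 100 such splits, the real one, gave as many (highest other 1373), with the same limit. On group means limma called 0 genes for a different rhythm, with 1680 at an unadjusted p under 0.05. For 5491 genes the change from ZT0 to ZT24 differed between SD and Ctrl by the test of that difference.

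Among the other counts, the averaged comparison called 11857 genes, and 1 of 100 splits, the real one, gave as many (highest other 3530). When whole groups were exchanged, 1 of 64 splits, the real one, gave the 2875 genes called on group means (highest other 0), so chance can be excluded for groups. The 100 splits part libraries of a group that lie close together, which favours lower counts, so they add little to this. In Ctrl 1 of 100 shuffles of the times over the libraries, the real one, gave 9767 rhythmic genes (highest other 200). These shuffles part libraries of a group that lie close together, so they speak for differences between groups and not for a rhythm. With whole Ctrl groups reordered the highest other count was 9099. In SD 2 of 100 shuffles gave 1560 or more (highest other 2050). This too speaks for differences between groups and not for a rhythm, since 76 of 100 orders of the whole SD groups gave as many. Comparisons of 3 with 3 libraries have 10 splits, which cannot give a share under 0.05. Their real counts and highest other counts were 6393 and 1 at ZT0, 6656 and 0 at ZT4, 9506 and 0 at ZT8, 8286 and 1 at ZT12, 9524 and 0 at ZT16, 10423 and 14 at ZT20, and 7933 and 4 at ZT24. For ZT24 against ZT0 they were 2190 and 1 in Ctrl and 6537 and 988 in SD.

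The 3 libraries of a group lay very close together, with a median SD within groups of 0.0845 log2 units in Ctrl and 0.0782 in SD. A single library deposited 3 times is argued against: the lowest of the 42 pairs had a median squared count difference of 1.493 times its Poisson variance, where copies with fresh counting noise give about 1. Libraries made from 1 tissue sample or pool per group remain a candidate explanation in Ctrl: immunoglobulin variable segments, whose use differs between animals, differed within groups 0.941 times as much as genes of like read count (1.131 over all 42 pairs), while their SD was 1.71 between Ctrl groups and 0.245 within. In SD that explanation stays open, since these 137 segments differed no more between groups (0.208) than within (0.224), and the ratio, 1.256 over the SD pairs, ran from 2.55 to 4.65 within SD ZT16, on 12 to 13 segments. The design names no biological explanation, and none was tested.

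For the plasma cell and mucous genes that were high in Ctrl at ZT8, ZT12, ZT16 and ZT24, a 24 h rhythm alone is argued against. The plasma cell list stood 1.833 and the mucous list 2.827 log2 units higher at Ctrl ZT24 than at Ctrl ZT0, the same clock hour. Both lists were made after these values were seen, so this difference is part of the pattern itself and not a separate test of it. Lymphoid tissue taken along is argued against at ZT12 and ZT24, where the B cell list rose by 0.0504 and 0.0631 over Ctrl ZT0, and more conducting airway at ZT16 and ZT24, where the higher of the club and ciliated medians stood at -0.325 and 0.0486. At ZT8 and ZT12 more airway stays open, since ciliated genes rose there by 0.984 and 0.616 while club genes stood at 0.105 and -0.291. At ZT8 and ZT16 lymphoid tissue stays open for the plasma cell genes only, since the B cell list rose by 0.671 and 1.229 and the T cell list by 0.406 and 0.782, while mucous genes, which are not lymphoid, rose by 4.14 and 2.52. A difference in immune state between the animals of these groups also stays open and was not tested.

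Fewer genes fitted a 24 h cosine in SD (1560) than in Ctrl (9767), a gap that was smaller with array weights (3909 and 9849) and with the plasma cell score (4288 and 7429), and that turned with the one-way F test (13516 and 12595). A stopped core clock is argued against, since the median ratio of SD to Ctrl amplitude over the core clock list was 0.8914. Of 100 orders of the 7 Ctrl groups, 1, the real one, gave as many genes as the Ctrl count (highest other 9099, median 3196). This argues against Ctrl differences scattered over the times without order as its source. It cannot exclude a difference shared by adjacent groups, which can fit a cosine without a rhythm. The Ctrl groups at ZT8, ZT12 and ZT16, high in plasma cell and mucous genes, are adjacent. Larger departures of SD group means from the cosine may account for part of the gap, as the residual SD around the cosine was 1.142 times as large in SD. In SD 76 of 100 orders of the 7 groups gave as many genes as the real order and the highest gave 8216, so chance cannot be excluded there. The SD groups differ by the one-way F test, but whether by any pattern over time was not tested.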

How the results depend on the processing

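The tests with total reads, voom, group means, the plasma cell score, the sign-flip test and without ZT8, ZT12, ZT16 and ZT24 were chosen only after the result was seen. Over the libraries left out in turn, each count kept within 1.5 times its value, but some named calls were lost: the Nr1d2 shift in 27 of 42 fits, Etfb and the alveolar type 1 list in 19 each, and mt-Tr and Mir6999 in 4 of 6 each. The averaged count ran from 11754 to 11981, rhythmic genes in Ctrl from 8974 to 10010 and in SD from 1228 to 1526, a different rhythm from 4571 to 5415, and the clock shift from 0.650 to 0.914 h. Counts at single times and for ZT24 against ZT0 kept within 1.5 times their values under each setting run on them, ZT0 from 5167 with only its 6 libraries to 7292 with array weights. Within that range too, 19 lists were called with an estimated correlation, against 27, and 24 without ZT8, ZT12, ZT16 and ZT24, not all of them among the 27. A fit with only 2 libraries in a group takes the spread from the other groups. Rescaling by median of ratios moves hardly anything (9766 rhythmic genes in Ctrl against 9767), because the deposited scaling is already that. It therefore says nothing about stability. With the replicate block the averaged count was 11888 and the rhythmic counts 9363 and 1228, and of the named genes and lists only the alveolar type 1 list and the Nr1d2 shift lost their calls. The numbers do not pair the libraries: residuals of the same number correlated by 0.00176 on average and 17 of 42 libraries lay closest to their own number. A comparison of 2 count models was not run. The deposited values are FPKM, and of count models only limma-voom was run, on the recovered reads. The calls of mt-Tr at ZT0 and of Mir6999 in SD at ZT24 against ZT0 were lost with array weights and without the filter.

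Counts that left this range were few. On group means 2875 genes were called for the averaged effect, 385 and 2 for rhythm in Ctrl and SD, and 0 by limma for a different rhythm (1680 at an unadjusted p under 0.05), which follows in part from the fewer units. The exact sign-flip test called 0 lists, its smallest possible p being 0.0156 and its smallest adjusted p 0.0526, which follows in part from that floor. Rhythmic genes in SD numbered 3909 with array weights, 4288 with the plasma cell score and 13516 with the one-way F test, which takes any change over time. A different rhythm was called for 3403 genes with the plasma cell score. The median clock shift kept its sign but was 0.362 h with array weights and 0.399 h with the plasma cell score, against 0.755 h. Except where the construction shows it, the cause was not tested.

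Some directions reversed, and the cause was not tested. The amplitude difference of Cobl was -0.00404 with a pseudocount of 0.1, -0.0239 without ZT24 and -0.0312 scaled by total reads, and ran from -0.0135 to 0.0286 over libraries left out. That of Gata5 was -0.00605 without ZT24, and that of Gata6 -0.00486 without ZT24 and -0.0264 scaled by total reads. Scaled by total reads, Acsl4 stood at -0.00128, Hadha at -0.0533, Hadh at -0.0144 and Etfa at -0.00578. Without ZT8, ZT12, ZT16 and ZT24, Cxcl13 stood at 0.0782, Bhlhe41 at 0.0890, Ciart at -0.263 and Hadh at -0.0575, and the list medians were -0.0632 for immediate early genes, -0.108 for alveolar type 1, -0.134 for mesothelial and 0.0196 for cardiac muscle.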

Other observations

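The hours of the lists below were looked at only after the result was seen, and no further tests of explanations were run on them. Alveolar macrophage genes were higher in SD at ZT4 (9 of 12 higher, median log2 0.52, adjusted p = 2.14e-06, and 0.00292 with an estimated correlation) and lower at ZT16 (11 of 12 lower, median -0.79, adjusted p = 7.66e-07, and 0.00157 with an estimated correlation). Inflammatory cytokine genes were higher at ZT4 (11 of 19, median 0.23, adjusted p = 0.00852, and 0.0118 with an estimated correlation) and lower at ZT12 (13 of 19, median -0.46, adjusted p = 0.000300, and 0.000928 with an estimated correlation). Adipocyte genes were higher at ZT0 (7 of 10, median 0.63, adjusted p = 2.62e-07, and 3.42e-05 with an estimated correlation) and lower at ZT24 (8 of 10, median -0.58, adjusted p = 1.43e-05, and 0.000243 with an estimated correlation).

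Heat shock genes were lower at ZT12 (16 of 19, median -0.45, adjusted p = 2.57e-07, and 0.00141 with an estimated correlation) and higher at ZT24 (13 of 19, or 16 adjusted over the list alone, median 0.30, adjusted p = 8.63e-06, and 0.00374 with an estimated correlation). Immediate early genes were lower at ZT4 (14 of 22, median -0.31, adjusted p = 5.52e-08, and 0.00893 with an estimated correlation) and higher at ZT16 (16 of 22, median 0.55, adjusted p = 5.92e-07, and 0.0135 with an estimated correlation). Ciliated cell genes were lower at ZT4 (14 of 14, median -0.45, adjusted p = 1.66e-10, and 0.000136 with an estimated correlation), at ZT8 (14 of 14, median -0.58, adjusted p = 1.51e-06, and 0.00169 with an estimated correlation) and at ZT12 (13 of 14, median -0.72, adjusted p = 3.48e-08, and 0.000521 with an estimated correlation). The mean of the ciliated list was higher in SD at 4 of the 7 times. All 18 NRF2 targets were higher at ZT20 (median 0.79, adjusted p = 2.78e-09, and 0.00111 with an estimated correlation). Cirbp, a cold-inducible RNA-binding protein, changed by log2 0.571 and Rbm3 by 0.0493 in the averaged comparison. Mitochondrial genes took 1.19% to 4.96% of reads per library, with means of 2.85% in Ctrl and 2.26% in SD. At ZT4 they took 4.72% to 4.96% in Ctrl and 1.45% to 1.52% in SD, and the lowest value was that of Ctrl ZT20 replicate 2, whose group had 2.24% and 2.35% in the other libraries. Per library Scgb1a1, the main club cell secretion, took 1.08% to 4.35%.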
